A study of Homo sapiens with 40 samples.

How the data were processed

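The series measured RNA levels by quantitative PCR in blood mononuclear cells of 30 people with acute myeloid leukaemia (AML), a cancer of immature myeloid blood cells, and of 10 normal donors. Per the labels' protocols, mononuclear cells were purified on Ficoll, total RNA was extracted with a column kit, and 400 ng of RNA was reverse-transcribed before PCR on a custom panel. The instrument and its baseline and threshold settings were not given in the sources used here. The panel held 65 target genes, 3 reference genes (HPRT1, PPIH and TFRC) and control wells for genomic DNA, reverse transcription and PCR.

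The first deposited table gave the threshold cycle (Ct) of each well, the cycle at which its fluorescence crossed a threshold, with no normalization. The second deposited table gave the authors' fold change of each AML sample over the median of the normal samples, per the file headers. The normal median in that table was on a log2 scale, as a difference of cycles from the reference, per the file headers. The deposited fold changes were recomputed from the Ct table with a largest difference of 6.01e-08 on the log2 scale. That match required the geometric mean Ct of the 3 reference genes and a limit of 35 cycles in normal samples but not in AML samples. Fold changes were given for 1555 wells and left empty for 395 AML wells without a signal.

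Expression was computed here as the Ct of HPRT1 minus the Ct of the gene, a log2 scale on the assumption that product doubles in each cycle. Wells above 35 cycles or without a signal were set to 35 and counted as not detected. Of the common reference genes listed before the data were examined, only HPRT1 was on the panel, so it served alone. PPIH alone, TFRC alone and the mean of the 32 targets detected in all 40 samples were run as alternatives. The geometric mean of the 3 reference genes and the mean of HPRT1 and PPIH were added after the data were seen. The groups, tests, thresholds, gene lists and naming rule were set before the data were examined.

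Of the 65 targets, 58 were detected in at least 4 of the 40 samples and were tested. The difference in mean between 30 AML and 10 normal samples was tested with a two-sided permutation test of 100000 reassignments with seed 20. The p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The smallest p these permutations can give is 1e-05. Detection was compared with a two-sided Fisher's exact test over the 30 targets detected in some samples and not in others. Spread was compared with a permutation test of the absolute deviations from each group's median. Each list score was the mean over the tested members of a list, compared with the same permutation test. Errors of differences are standard errors with unequal variances. For limma fits they are limma's own standard errors, which assume equal variances in the groups.

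The text names up to 15 called genes with the largest increase and up to 10 with the largest decrease. It also names up to 3 members of each list with the smallest p, and a fixed set of AML antigens whether called or not. Up to 5 genes with the most AML samples above every normal donor, and members of the smallest covering sets, complete the 25 named genes. Genes outside this rule are named where a passage says so. Lists of granule proteins, cancer-testis antigens, cell cycle genes, progenitor surface proteins, apoptosis regulators, transcription regulators and solid tumour antigens had members on the panel. The lists of lymphocyte, monocyte, and erythroid and platelet genes had 0 members on the panel. HBG2, a fetal haemoglobin chain, was on the panel but outside the erythroid list as fixed, and no cell type was scored from it. The cell mix of the samples was therefore not measured. The cancer-testis list was matched partly by the start of the symbol, which brought in CTAGE5 and SSX2IP.

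Precision was set by cycles, since PCR gives no read counts. Triplicate control wells had a pooled SD of 0.201 cycles for reverse transcription and 0.207 cycles for PCR, and each target had a single well per sample. Shares of samples carry 95% Wilson intervals, which cover sampling of people only. Of the 65 target symbols, 61 were current in the RefSeq gene table of assembly GRCh38.p14, used for names only. The other symbols (BAGE, RAGE, CTAGE5 and HN1L) were kept as the files give them. RAGE has been used for more than 1 gene and was not resolved.

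The tests were checked on 10 simulated data sets of 58 genes with the sizes of the AML and normal groups. Both groups were drawn from the same pooled residuals, gene by gene, with no Ct limit applied, and only genes with a mean well above the limit were changed. Under those settings the permutation test called 86% of genes changed by 2 log2 units, 97% of those changed by 4 and 1.21% of unchanged genes. Genes with a changed spread were left out of the unchanged rate, so these rates do not cover unequal spread or values at the limit. The spread test called 28% of genes whose AML deviations had been widened 4-fold, so it misses most such genes at this sample size. Alternatives to the Ct limit, filter, reference, test and samples were run, including limma and a permutation test of ranks. A principal component analysis of the 32 targets was also looked at before the correlations among AML samples were chosen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, R 4.3.3 and limma 3.58.1.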

Results

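Expression of 65 putative immunotherapy targets was measured by quantitative PCR in blood mononuclear cells from 30 people with AML and 10 normal donors. Of 2600 target wells, 543 (20.9%) gave no signal and a further 113 crossed the threshold after 35 cycles. The highest measured Ct was 39.8, and 32 targets were detected in all 40 samples. The Ct of HPRT1, a purine salvage enzyme used as the reference, was 25.02 ± 0.99 (SD, n = 30) in AML and 24.99 ± 0.51 (SD, n = 10) in normal samples. That difference of 0.03 ± 0.24 cycles (SE) did not pass a two-sided permutation test (p = 0.930).

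The main comparison asked which targets differ in level between AML and normal blood mononuclear cells. CCNA1, a cyclin otherwise used mainly in male meiosis, was higher in AML by 6.77 ± 0.69 log2 units (SE), and by 7.77 with a Ct limit of 40 and 6.05 with 33. WT1, a zinc finger transcription factor, was higher by 6.05 ± 0.70, and PRTN3, a serine protease of neutrophil granules, by 5.47 ± 0.77. With WT1 undetected in 9 of 10 normal samples, its difference followed the Ct limit, at 9.99 with a limit of 40 and 4.37 with 33. BAALC, a gene of haematopoietic progenitors, was higher by 3.43 ± 0.70 and FLT3, a receptor tyrosine kinase of progenitors, by 2.90 ± 0.47. RPS23, a protein of the small ribosomal subunit, fell by 0.94 ± 0.17, and EEF1G, a subunit of translation elongation factor 1, fell by 0.63 ± 0.14. Cell mix was not measured, so none of these differences separates a change per cell from a different share of cells that express the gene.

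Of 58 tested genes, 9 were higher in AML, 2 were lower and 47 were not called, with 15 at an unadjusted p under 0.05. The adjusted p was 1.93e-04 for CCNA1, WT1 and MUC1, whose unadjusted p of 1e-05 is the smallest the permutations can give. MUC1, a membrane mucin, was higher by 2.16 ± 0.31 log2 units, and all 30 AML samples lay above the normal mean. CDC25C, a phosphatase that starts mitosis, was higher by 1.95 ± 0.50 (adjusted p = 0.0190, permutation test), with 26 of 30 AML samples above the normal mean. HMMR, a hyaluronan receptor that also binds the mitotic spindle, was higher by 1.05 ± 0.36 with an adjusted p of 0.0495. HMMR kept its call in 20 of 40 runs that each left out 1 sample. HN1L was higher by 2.26 ± 1.15 (adjusted p = 0.0190), but that call was lost when undetermined wells in normal samples were treated as missing, with a difference of 0.58.

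Leaving out 1 sample at a time kept the call of HN1L and of EEF1G in 38 of 40 runs each. RPS23 lay below the normal mean in 27 of 30 AML samples (adjusted p = 0.00454) and EEF1G in 25 of 30 (adjusted p = 0.0212). With the Ct of the PCR and reverse transcription control wells as covariates in limma, neither gene was called, at -0.70 for RPS23 and -0.56 for EEF1G. The same fit ended 3 of the 9 higher calls, CDC25C (1.86, adjusted p = 0.0823), HMMR (0.92, 0.135) and HN1L (1.98, 0.101), and kept 6. The PCR control wells themselves had a Ct 0.39 ± 0.14 cycles (SE) higher in AML samples (p = 0.00679, adjusted p = 0.0611, permutation test). Their Ct lay below the median of all samples in 12 AML and 8 normal samples. It lay at or above that median in 18 AML and 2 normal samples, so control-well Ct was not balanced between the groups.

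**Figure D1:**
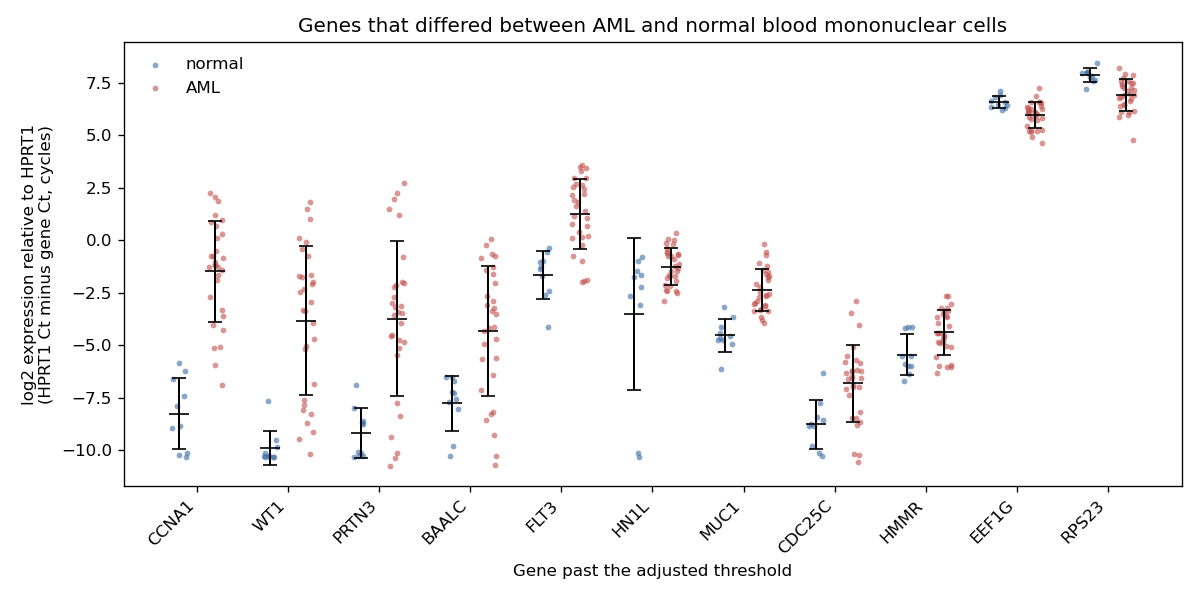
Each point is 1 sample, in arbitrary order, for the genes that passed the adjusted threshold; the vertical axis is log2 expression relative to HPRT1, and bars give the mean and SD of 30 AML and 10 normal samples. CCNA1 lay above every normal donor in 28 AML samples, while the normal group of HN1L was spread by 2 samples without a signal.

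The reference gene set the balance of higher and lower calls. With HPRT1, 81.8% of calls were higher in AML and the median difference over tested genes was 0.30. With TFRC, the transferrin receptor, 6 genes were higher and 21 lower, so that 22.2% of calls were higher, and the median difference was -0.77. With the authors' geometric mean of HPRT1, PPIH and TFRC, 6 were higher and 7 lower (46.2% higher, median -0.16). PPIH, a cyclophilin of the spliceosome, gave 7 higher and 3 lower (70.0%). The mean of targets detected in all samples gave 9 higher and 5 lower (64.3%), with a median of 0.13. TFRC relative to HPRT1 was higher in AML by 1.07 ± 0.41 (p = 0.0314, adjusted p = 0.0708, permutation test). CCNA1, WT1, PRTN3, BAALC, FLT3 and MUC1 were called higher, and RPS23 and EEF1G lower, under all 6 references. HMMR had a difference of -0.018 with TFRC, against 1.05 with HPRT1, and lost its call under each of the 5 other references. Beside TFRC (adjusted p = 0.994) these were PPIH (0.84, adjusted p = 0.157), the mean of targets detected in all samples (0.89, 0.0828), the geometric mean (0.59, 0.317) and the mean of HPRT1 and PPIH (0.95, 0.0782). HN1L lost its call with TFRC, with PPIH (adjusted p = 0.0515) and with the geometric mean (0.0637), and CDC25C with TFRC (0.330) and the geometric mean (0.0637). By ranks, HMMR and HN1L were not called (adjusted p = 0.0834 for each, permutation test). At a Ct limit of 40, BAALC (3.59, adjusted p = 0.0583), CDC25C (2.46, 0.0992) and HMMR (1.05, 0.0583) were not called, although none of these differences was smaller than at 35.

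**Figure D2:**
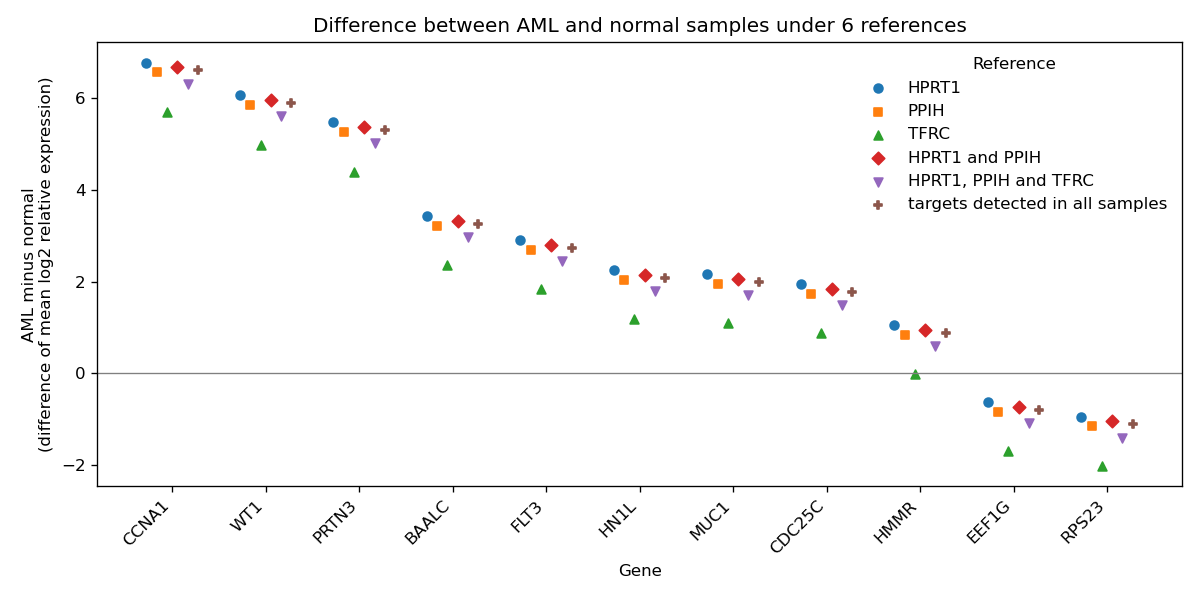
Points give the AML minus normal difference of mean log2 relative expression for each called gene, with 1 symbol per reference; no error bars are drawn. TFRC gave the lowest value for every gene shown, and RPS23 ranged from -2.01 with TFRC to -0.94 with HPRT1.

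In the list named transcription and chromatin regulators, 2 of 4 tested members rose (WT1 and BAALC), 0 fell and 2 did not pass. Adjusted over the list alone, 2 were higher. Membership followed the list fixed before the data were examined, and no role of BAALC in transcription was shown here. The list score was higher in AML by 3.27 ± 0.57 (adjusted p = 3.50e-04, permutation test). HOXA9, a homeobox factor of progenitors, differed by 2.21 ± 1.01 (adjusted p = 0.348; 1.25 with a Ct limit of 40 and 2.73 with 33), and BMI1, a polycomb protein, by 1.39 ± 1.19 (adjusted p = 0.198). The BMI1 difference rested on 1 normal well without a signal and was 0.23 with that well treated as missing. PRTN3 was the single granule protein measured and FLT3 the single progenitor surface protein; both rose.

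Of 12 tested cancer-testis antigens, 1 rose (CCNA1), 0 fell and 11 did not pass, and 1 was higher when adjusted over the list alone. Their score was higher by 1.09 ± 0.31 (adjusted p = 0.00977, permutation test). That call was lost with TFRC as the reference (0.023, adjusted p = 0.957) and with the geometric mean of 3 reference genes (0.64, adjusted p = 0.0539). CCNA1, at 6.77, weighed most in this mean, against a median difference of 0.54 over the 12 members. No score without CCNA1 was computed, so a rise of the class as a whole was not shown. PRAME, a repressor of retinoic acid signalling, differed by 2.88 ± 1.17 (adjusted p = 0.193), or by 4.88 with a Ct limit of 40 and 2.10 with 33, and RAGE by 1.56 ± 0.61 (adjusted p = 0.256). The symbol RAGE has named more than 1 gene.

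Of the 7 members of the cell cycle and mitosis list, 1 rose (HMMR), 0 fell and 6 did not pass, and 2 were higher when adjusted over the list alone. CDC25C (1.95) and the cyclin CCNA1 (6.77), both called higher, were outside this list as fixed before the data were examined. The score of the 7 list members was higher by 0.69 ± 0.28 (adjusted p = 0.0373, permutation test), and was -0.38 with TFRC as the reference. That call also ended with PPIH (adjusted p = 0.0874), with the geometric mean of 3 reference genes (0.502), at a Ct limit of 40 (0.0640) and with the median over members (0.0797). CCNE1, the cyclin of S-phase entry, differed by 1.06 ± 0.34 (adjusted p = 0.0599). It was called with the mean of targets detected in all samples as reference (adjusted p = 0.0234), by ranks (0.0447) and without 4 AML samples whose label carries the suffix PB (0.0205). Leaving out the normal donor with the highest HPRT1 Ct (adjusted p = 0.0416) or the one with the fewest undetermined targets (0.0224) also gave a call for CCNE1. By permutation test CCNE1 was not called with TFRC (-0.009, adjusted p = 0.994), PPIH (0.85, 0.0962) or the geometric mean of 3 reference genes (0.60, 0.181). Nor was it called in limma with control-well covariates (0.998, adjusted p = 0.135). AURKB, a kinase of chromosome segregation, differed by 1.12 ± 0.42 (adjusted p = 0.149). BIRC5, a survival and mitosis factor, differed by 1.17 ± 0.60, TERT, the telomerase catalytic subunit, by 0.36 ± 0.31 and AURKA, a spindle pole kinase, by 0.03 ± 0.39; none passed. BIRC5 was not detected in 7 of 10 normal samples, and its difference was 2.69 with a Ct limit of 40 and 0.45 with 33. TERT was at -0.38 with a limit of 40.

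Neither apoptosis regulator passed: BCL2 differed by -0.48 ± 0.42 and MCL1 by -0.64 ± 0.36, and their score by -0.56 ± 0.31 (adjusted p = 0.130, permutation test). That score was called lower under the 4 other references run for it, at -0.77 with PPIH (adjusted p = 0.00570), -0.72 with the mean of targets detected in all samples (0.00110), -1.01 with the geometric mean (4.50e-04) and -1.63 with TFRC (3.50e-04). With TFRC, BCL2 (-1.55) and MCL1 (-1.71) were each called. Of 5 solid tumour antigens, 1 rose (MUC1), 0 fell and 4 did not pass, with 1 higher when adjusted over the list alone. Their score differed by 0.47 ± 0.38 (adjusted p = 0.278, permutation test), with CA9, a carbonic anhydrase, at 0.71 ± 0.41 (2.03 with a Ct limit of 40 and 0.28 with 33) and RPSA, a ribosomal protein and laminin receptor, at -0.50 ± 0.30. RPSA was called lower with TFRC (-1.57) and with the geometric mean (-0.96).

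Detection was compared as the share of samples with a Ct under 35. WT1 was detected in 28 of 30 AML samples (93.3%, 95% Wilson interval 78.7 to 98.2) and in 1 of 10 normal samples (10.0%, 1.79 to 40.4). It was the single call among 30 genes (adjusted p = 5.68e-05, Fisher's exact test), with 4 genes at an unadjusted p under 0.05. PRTN3 was detected in 26 of 30 AML and 5 of 10 normal samples (adjusted p = 0.214, Fisher's exact test), so its difference in level is partly set by the Ct limit (6.38 with a limit of 40 and 4.39 with 33).

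Spread was compared to ask how evenly a target is expressed over people with AML. The mean absolute deviation from the group median was wider in AML for WT1 (2.93 against 0.40 log2 units) and for HOXA9 (4.45 against 1.18), both with an adjusted p of 0.0200 in a permutation test. The normal spread of WT1 was fixed by the limit, since 9 of 10 normal values were set to it, so the comparison for WT1 does not measure spread in normal cells. HOXA9 was detected in 23 of 30 AML samples and in all 10 normal samples, and 16 AML samples lay above every normal donor while 10 lay below every one. With a Ct limit of 40 in place of 35, 0 genes were called by this permutation test, with 8 at an unadjusted p under 0.05.

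Each AML sample exceeded every normal donor for a median of 13.5 genes (range 3 to 27). That median was 7 with a margin of 2-fold and 5.5 with the normal mean plus 3 SD as the threshold. A normal donor exceeded the other 9 for a median of 3 genes (range 0 to 33). The donor with 33 genes had 9 with PPIH as reference, 2 with TFRC, 13 with the geometric mean and 5 with the mean of targets detected in all samples. Chance alone would put 9.09% of exchangeable values above 10 others. CCNA1 exceeded every normal donor in 28 AML samples (93.3%), FLT3 in 25, PRTN3 in 24, and BAALC, MUC1 and WT1 in 23 each. HBG2, a fetal haemoglobin chain, did so in 15 samples, with a mean difference of 3.51 ± 1.26 that did not pass (adjusted p = 0.158, permutation test). Whether HBG2 tracked erythroid cells in the samples was not tested. Without the 4 AML samples with the suffix PB, whose meaning the labels do not give, HBG2 was called (4.66, adjusted p = 0.0205, permutation test). With a margin of 2-fold, 3 genes were needed for every AML sample to exceed all normal donors in at least 1 of them, and 13 sets of that size did so. CCNA1 alone covered 26 samples, FLT3 added 3 and WT1 added 1. Without the normal donor with the fewest undetermined targets, 2 genes sufficed, as they did without the donor with the highest HPRT1 Ct and with the mean of targets detected in all samples as reference. These sets describe the 30 samples they were chosen on.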

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

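The tests of failed wells, control wells and TFRC, the split count for called genes, and the geometric mean and the mean of HPRT1 and PPIH as references were chosen after the results were seen. The references PPIH, TFRC and the mean of targets were planned, and the counts of other sample splits for spread, detection and list scores were set before those splits were drawn.

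In 35 groups of 10 normal samples examined, 7 had 1 sample far from the others relative to the range of the group, where chance flags about 1 in 20 groups. BMI1 had 1 low normal sample, a well without a signal, with a gap of 0.863 of the range. WT1 (0.693), CA9 (0.477) and PRAME (0.475) each had 1 high normal sample; most normal values of these genes were set to the 35-cycle limit (not detected in 9, 9 and 7 of 10), so the rate of 1 in 20 does not apply to them. The Ct of HPRT1 had 1 high normal sample (0.488). The number of undetermined targets was lowest in 1 normal donor (0.667 of the range). The number of genes above the other 9 normal donors was highest in 1 normal donor (0.758), with 33 genes relative to HPRT1 and 2 to 13 under the 4 other references compared. These last flags fell on the same donor, which was not the donor with the highest HPRT1 Ct.

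HN1L was higher in AML by 2.26 log2 units, and 2 normal wells without a signal stood among wells that otherwise gave a clear one. With undetermined wells of such genes treated as missing, the difference was 0.58 (adjusted p = 0.277), so failed wells may account for most of it. A difference between AML and normal cells was not excluded for the remainder.

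RPS23 and EEF1G were lower in AML. Both stayed called under the 5 other references, where the highest adjusted p of either gene was 0.0361 (permutation test). Each of those references gave lower values than HPRT1, with EEF1G at -0.73 to -1.70 and RPS23 at -1.04 to -2.01. A lower value was thus favoured in advance, and these references cannot exclude the choice of reference gene. Plate or run differences stay open. Adding control-well Ct as covariates in limma moved RPS23 from -0.94 ± 0.26 to -0.70 ± 0.28 (limma SE). EEF1G moved from -0.63 ± 0.22 to -0.56 ± 0.25, and neither gene was called with the covariates. Among the 20 samples with a PCR control Ct below the median, RPS23 stayed called (-0.71, adjusted p = 0.0259, permutation test) and EEF1G did not (-0.42, adjusted p = 0.103). The panel held no lymphocyte or monocyte markers, so a shift in cell types could not be tested either. That limit holds for the 9 higher genes as well.

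More genes were lower in AML when TFRC was in the reference. TFRC itself was higher in AML by 0.90 ± 0.32 relative to the mean of targets detected in all samples, at p = 0.0232 and an adjusted p of 0.0695 over 3 reference genes (permutation test). Relative to the same mean, HPRT1 differed by -0.17 ± 0.22 and PPIH by 0.044 ± 0.12, where a shift of the targets alone would have moved all 3 reference genes by about 0.90. By construction, using TFRC in place of HPRT1 lowered each difference by 1.07, the group difference of TFRC relative to HPRT1 in these samples. Whether TFRC differs between AML and normal cells beyond these samples stays open, since its difference did not pass the adjusted threshold.

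Chance assignment of people to groups was examined by splitting the 40 samples into 30 and 10 in 100 ways, the real split included. Only 1 split, the real one, gave as many called genes (11 against at most 6 in any other split). The same held for detection (1 against 0) and, with HPRT1 as the reference, for list scores (3 against 1). No other split drawn reached these 3 counts. The splits reassign group labels as the tests behind the calls in effect already did, so they are not separate evidence against chance. For wider spread 1 split, the real one, gave 2 genes against at most 1, but WT1 was set by the Ct limit. HOXA9 alone equals the highest count of another split, although 96 other splits gave no spread call. The rule set before was for 2 genes and not for HOXA9 alone, so chance is left open for spread.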

How the results depend on the processing

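The geometric mean of 3 reference genes, the mean of HPRT1 and PPIH, the missing-well setting, omitted single donors, the control-well settings, and TFRC and PPIH for list scores were chosen after the data were seen. Among 612 values of named genes and lists, 534 kept their side of the threshold, 18 of them with a change of sign but no call in either setting. A further 47 lost a call, 27 gained one and 4 reversed, and the cause was not tested unless stated. The 534 include genes called in neither setting, and only 11 of the 25 named genes were called in the main setting. That share therefore does not measure how firm the calls are. With TFRC as reference, AURKA was -1.04, HMMR -0.018 and the cell cycle score -0.38, and AURKA was -0.50 in the authors' fold changes. Genes lower in AML numbered 21 with TFRC, 5 with the mean of targets detected in all samples and 7 with the geometric mean of 3 reference genes, against 2. A sign-flip test of the authors' fold changes gave 15 higher and 22 lower; it ignores the spread of normal samples. Lower genes numbered 1 without the normal donor with the fewest undetermined targets, 1 among the 20 samples with a low PCR control Ct, and 0 with control-well covariates, which also left 6 of 9 higher genes. Leaving out each sample in turn gave 7 to 10 higher and 1 to 3 lower genes. Sample numbers 1 to 10 occur in both groups but belong to different people, and 4 of 10 same-numbered pairs correlated above 0.1 (range -0.39 to 0.31), so they do not pair. With the replicate block on those 20 samples, limma called 7 higher and 0 lower genes, against 9 and 1 without it; the 1 was DDX43, and RPS23 (-0.58) and EEF1G (-0.42) were called in neither fit. Detection calls numbered 4 at a Ct limit of 33, against 1, and spread calls 0 at a limit of 40, against 2. The median number of genes above normal per AML sample was 5.5 with the normal mean plus 3 SD and 7 with a 2-fold margin, against 13.5. The Ct limit bounds every difference for genes undetected in normal samples.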

Other observations

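The genes in this part lie partly outside the naming rule and were chosen after their values were seen, as were the correlation tests and the geometric mean as reference; the tests of level and spread and the other references were planned.

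NRAS and HRAS, which encode growth-signalling GTPases, differed by -0.33 ± 0.17 and -0.05 ± 0.26 log2 units (SE), and neither was called with HPRT1 as the reference; NRAS was called lower with TFRC, the geometric mean of 3 reference genes and the mean of targets detected in all samples, and HRAS with TFRC. NPM1, a nucleolar chaperone, differed by -0.077 ± 0.27 and was called lower with TFRC. MSLN, a surface protein of mesothelium, had wide spread in both groups, with an SD of 4.68 in AML and 3.47 in normal samples around a difference of -0.16 ± 1.39. HOXB4, a homeobox factor of progenitors, had a mean absolute deviation of 2.84 in AML against 0.92 in normal samples (adjusted p = 0.0851, permutation test), which did not pass; it passed with the mean of targets detected in all samples as reference.

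A principal component analysis of the 32 targets detected in all samples, run over all 40 AML and normal samples, had been examined first. FLT3 (absolute loading 0.625) and MUC1 (0.335) led component 1 (24.5% of variance). RPS23, EEF1G, AURKB and RPSA completed its 6 strongest loadings. HMMR, AURKB and CCNB1 led component 2 (14.3%). The 7 correlations that followed used these genes over the 30 AML samples, so high values among them were built into the choice and are given as description. To avoid a shared reference well, the first gene was taken relative to HPRT1 and the second relative to PPIH.

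RPS23 and EEF1G had a Pearson r of 0.558 (adjusted p = 0.00290) and a Spearman rho of 0.412 (adjusted p = 0.0345), both by permutation test, and r was 0.425 without the 2 samples farthest from the median. For RPS23 and RPSA r was 0.627 and rho 0.555, with r 0.486 without those samples, and for EEF1G and RPSA r was 0.615 and rho 0.598, with r 0.519. HMMR had r 0.517 and rho 0.459 with CCNB1 (r 0.511 without 2 samples), and r 0.554 and rho 0.523 with AURKB (r 0.458). CCNB1 and AURKB had r 0.152 and rho 0.161 (adjusted p = 0.492 for r, permutation test). The translation and mitosis scores had r -0.0117 and rho -0.0194 (adjusted p = 0.950 for r, permutation test). Principal components are uncorrelated by construction over the 40 samples they were computed on. A value near 0 may thus have been favoured by the choice, and over the 30 AML samples it decides nothing.

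A hypothesis that cell cycle genes vary together over people with AML was chosen after these loadings were seen. It was put to the list fixed before the data were examined. Its 5 members detected in all samples (HMMR, CCNB1, CCNE1, AURKA and AURKB) had a mean pairwise correlation of 0.0974, against a median of -0.0417 over all 201376 sets of 5 among 32 targets. As high a value occurred in 8.34% of those sets, which leaves the hypothesis open; a shared proliferative state may exist but was not separated from chance.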
